A study of Mus musculus with 6 samples.

How the data were processed

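γδ T cells from the small intestinal epithelium (SI-IEL, intraepithelial lymphocytes) and from ear skin of mice were profiled by droplet single-cell RNA sequencing, with receptor sequencing from the same cDNA. The labels' protocols describe 1 pool of 19 mice per tissue, aged 6 to 16 weeks. In each pool, 7 wild-type mice (WT) carried hashtag antibody 1 and 12 mice with a knocked-in, already rearranged T cell receptor δ gene (KI) carried hashtag antibody 2. The strain label is Bl6-Tcrdtm(V6D2J1)TW. Live CD3+ TCRδ+ TCRβ− cells were sorted, and 10000 sorted cells of each genotype were loaded for SI-IEL. The number loaded for skin is not given in the sources used here. The series design text names spleen and the extra sorting markers B220 and CD11c, which differs from the tissue given with each sample. The tissue of the sample labels was used. Each tissue was thus 1 pool per genotype without replicates, so no p-value, standard error or count of changed genes over all genes is given. Within gene lists, members are counted by their counting interval. Intervals cover counting error only and not differences between mice.

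For each tissue the authors deposited a gene count matrix, the same matrix with 2 hashtag features, and a table of receptor contigs. Per the file headers, the matrices hold whole numbers, which are UMI counts per gene and cell without normalization, written by software version 3.0.2. The labels give build mm10. The gene counts of both matrices of a tissue were identical, with 0 differing entries. The deposited contig tables give read and UMI counts per assembled contig with its V gene, J gene and CDR3. The aligner, the annotation release behind the counts and the reference behind the contig names are not given in the sources used here. Chromosome positions were taken from GENCODE M21 by gene ID (mm10), in which 128 of the 128 genes looked up were found.

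Cells were assigned to a genotype with HTODemux (Seurat 5.3.0, quantile 0.99). Cells positive for 1 tag were kept if they had at least 500 genes and under 10% mitochondrial UMIs. In SI-IEL, 722 of 10206 barcodes (7.07%) were positive for both tags and 34 for none. In skin these were 8 (0.719%) and 23 of 1112. Doublets within a tag were not removed. From the doublets across tags, 459 WT and 284 KI doublets within a tag are expected in SI-IEL, and 1.29 and 12.4 in skin. Scrublet marked 0 of 10206 SI-IEL barcodes and 9 of 1112 skin barcodes, so it did not find the SI-IEL doublets that the tags show.

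The δ chain of a cell was its productive, high-confidence δ contig with the most UMIs. The knock-in chain was defined as the most frequent δ CDR3 of KI-tagged cells with a DV6-family V gene and TRDJ1. The planned γ V call from contigs could not be made, because TRGV2 was the only γ V gene named in the contig tables. A cell's γ V gene was therefore the γ V gene with the most UMIs in the expression matrix, with at least 2 UMIs and no tie. Clones shared the V gene, J gene and CDR3 amino acid sequence, and clone numbers were compared at equal cell number by rarefaction. Shares carry exact 95% Clopper-Pearson intervals (scipy 1.17.1). Where a count is 0, the share given as the limit is that of 3 cells.

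Cells of a tissue were clustered together with Scanpy 1.11.5. Counts were scaled to 10000 per cell and logged, 2000 variable genes without T cell receptor genes gave 30 principal components, and 15 neighbours were used with Leiden resolution 0.6 (leidenalg 0.10.2, seed 0). A cluster took a name from the fixed marker lists only with at least 3 markers of a class among its 50 leading genes and 2 among the first 10. Other clusters are given by number and leading genes.

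Counts were summed over the cells of a genotype and compared as the log2 ratio of CPM plus 1 (CPM, UMI counts scaled to the same total in every group), with a conditional binomial 95% counting interval, for genes with at least 50 UMIs over both genotypes. A gene with 0 UMIs in 1 group is given as a lower bound against 3 counts. Named genes were the 10 highest and 10 lowest ratios among genes with at least 50 CPM in either genotype, leaving out T cell receptor, ribosomal protein and mitochondrial genes, and the extremes of each fixed gene list. By γ V gene and by tissue, 5 each way were taken. Gene lists needed 5 measured members, and their median ratio is given with a counting interval from 1000 Poisson draws. Its percentile refers to 10000 random lists matched on expression, and describes these libraries only. Members with 0 UMIs in 1 group changed no list median by being set at their bound unless stated. Genes were called higher or lower when their counting interval excluded 0.

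The method was tested on simulated data. In SI-IEL, genes with simulated folds of 0.25, 0.5, 2 and 4 gave median log2 ratios of −1.86, −0.93, 0.97 and 1.95, and the intervals covered the true value for 95.7%, 95.8%, 96.0% and 100% of them. In skin the medians were −1.94, −0.97, 1.00 and 2.01, with 97.2%, 92.5%, 98.0% and 96.0% covered. For 200 unchanged genes the interval included 0 for 91% in SI-IEL and 98.5% in skin. In this draw, unchanged SI-IEL genes were thus called higher or lower more often than a 95% interval states. Summed counts were simulated as Poisson counts, which is the model of the interval. The simulation therefore does not test the calls for genes whose UMIs lie mostly in single cells.

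Comparisons, gene lists, marker lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives changed the tag rule, the cell filter, contig filter, clone definition, clustering, scaling, pseudocount, low count filter, cell weights and γ V composition. Scaling by TMM used edgeR 4.0.16 and median-of-ratios scaling used DESeq2 1.42.0. Chosen after the data were seen were the γ V call from expression, the naming thresholds for clusters, the table of δ chains by γ V gene, and several alternatives. These were to leave out the 200 most differing genes from the clustering, clusters of other cell types, skin cluster 7 or the 20 most frequent WT δ clones, to use WT cells with Xist and without Y-linked UMIs, and to equalise γ V shares for the lists. Contigs of other receptor loci were counted and used in no comparison. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and matplotlib 3.10.9.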

Results

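The data comprised a gene expression, a hashtag and a receptor library for each of 2 tissues, each from 1 pool of WT and KI mice. SI-IEL gave 5102 WT and 4018 KI cells with 14351754 and 11819870 UMIs. Skin gave 258 WT and 796 KI cells with 989022 and 3189996 UMIs. Median depth was alike between genotypes, with 2626 and 2753 UMIs per cell in SI-IEL and 3493 and 3460.5 in skin. UMIs of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d or Uty were found in 25.1% of WT and 0.324% of KI cells in SI-IEL, and in 20.5% and 0.754% in skin. Xist, the RNA that silences an X chromosome in female cells, was found without Y-linked UMIs in 33.0% of WT and 79.7% of KI cells in SI-IEL, and in 51.2% and 78.0% in skin.

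The first comparison asked whether KI cells carry 1 shared δ chain. Nearly all did in SI-IEL. The δ CDR3 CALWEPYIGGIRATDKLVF, joined from TRAV15D-1-DV6D-1 and TRDJ1, was the top δ contig in 3148 of 3335 SI-IEL KI cells with a δ contig (94.4%, 95% interval 93.6 to 95.1). WT cells had it in 24 of 4424 (0.542%). In skin it was the top contig of 398 of 488 KI cells (81.6%, 77.8 to 84.9) and 1 of 197 WT cells. Counting any δ contig of a cell, 98.1% of SI-IEL and 89.96% of skin KI cells carried it. A further δ contig beside it was found in 211 SI-IEL and 45 skin KI cells. The chain was found in cells of each frequent γ V call, which rests on expression and does not show the paired γ chain. In SI-IEL KI cells its share was 93.8% with Tcrg-V1 (256 of 273), 92.5% with Trgv2 (681 of 736), 91.4% with Tcrg-V4 (74 of 81) and 95.6% with Tcrg-V7 (1663 of 1740). In skin KI cells with Tcrg-V5, the γ V gene of epidermal γδ T cells, it was 82.4% (229 of 278, 77.4 to 86.7). Of 158 WT skin cells with Tcrg-V5 and a δ contig none had it, and 123 (77.8%) had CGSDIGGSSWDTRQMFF.

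WT cells used many δ chains in the intestine and few in skin. In SI-IEL WT cells the most frequent δ V genes were TRDV2-2 (36.1%), TRAV15D-1-DV6D-1 (18.9%), TRAV15D-2-DV6D-2 (16.4%) and TRDV5 (13.6%). WT skin used TRDV4 in 178 of 197 cells (90.4%), with 1 clone, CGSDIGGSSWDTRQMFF, in 142 (72.1%). At 3335 cells, SI-IEL WT cells had 1315 δ clones and KI cells 162. At 197 cells, skin WT cells had 28 and KI cells 24.5. Expression of several V genes showed the same difference. In SI-IEL KI cells, Trdv2-2 was at a log2 ratio of −2.40 to WT and Trdv5 at −3.30, while Trav15-1-dv6-1 was at 1.54. In skin, Trdv4 was at −3.44, with 1599 KI and 5396 WT UMIs, and Trav15-1-dv6-1 at 4.68. Trav15d-1-dv6d-1, the V gene named for the knock-in chain, did not follow this in SI-IEL. There it was at −0.21 (−0.65 to 0.17), with 86 KI and 123 WT UMIs. In skin it had 373 KI and 0 WT UMIs (at least 38.5-fold). Trav15-1-dv6-1 and Trav15d-1-dv6d-1 are near-identical, so UMIs of either can come from the other.

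The γ V genes were then compared, to ask whether cells with 1 δ chain use the same γ chains. Tcrg-V7, the V gene typical of intestinal γδ T cells, was called in 48.0% of WT and 48.7% of KI SI-IEL cells. Tcrg-V1 was called in 4.02% of WT (3.50 to 4.59) and 8.11% of KI cells (7.29 to 9.001), Trgv2 in 24.3% and 22.2%, and Tcrg-V4 in 3.19% and 2.46%. In skin, Tcrg-V5 was called in 73.3% of WT (67.4 to 78.6) and 52.6% of KI cells (49.1 to 56.2). Tcrg-V1 was called in 6.41% of KI cells and 0 of 258 WT cells, which allows a share of up to 1.16% (3 cells). In 4 WT cells at least 2 Tcrg-V1 UMIs were found without giving the call. Trgv2 was called in 1.55% of WT and 4.65% of KI skin cells, Tcrg-V7 in 0 of 258 WT and 2.14% of KI cells, and Tcrg-V6 in 1.94% and 1.88%. Of the KI skin cells, 9 of the 17 with Tcrg-V7 and 5 of the 37 with Trgv2 were in cluster 7, where 3 of 16 cells with a δ contig carried the knock-in chain. No call was made in 20.01% and 17.9% of SI-IEL and 20.9% and 31.0% of skin WT and KI cells. As background, 0 of 14 cells of the SI-IEL B and plasma cell cluster, with a median of 6125.5 UMIs, had a Tcrg-V7 or Trgv2 call. In the skin myeloid cluster, with a median of 7011.5 UMIs, 33 of 74 cells (44.6%) had a Tcrg-V5 call. Its depth was 202% of the library median and δ contigs were found in 33 of its cells, so these calls do not measure background alone. Tcrg-V1, Trgv2 and Tcrg-V3 are near-identical in sequence, so calls among them are less certain. Calls also hide further V genes in a cell. At least 2 Trgv2 UMIs were found in 57.1% of WT and 58.5% of KI SI-IEL cells. At least 2 Tcrg-V4 UMIs were found in 13.0% and 12.5%.

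Among γ contigs named TRGV2, more clones were found in KI than in WT SI-IEL cells at equal cell number. Such contigs were found in 1366 of 5102 WT and 1129 of 4018 KI cells, so γ V genes of unlike sequence are not covered. Whether the name also took in the near-identical Tcrg-V1 and Tcrg-V3 was not tested. If it did, the pooled clone numbers mix V genes whose shares differed between genotypes, as Tcrg-V1 calls did (4.02% and 8.11%). The KI pool held 12 mice and the WT pool 7, so genotype and pool size cannot be separated in this comparison. Contigs named TRGV2 held 265.75 clones in WT and 425 in KI cells at 1129 cells each. With TRGJ2 there were 173 and 258 clones at 711 cells, and with TRGJ4 67 and 114 at 259 cells. The most frequent WT clone, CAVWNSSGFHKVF, took 15.3% of cells (13.4 to 17.3). The most frequent KI clone, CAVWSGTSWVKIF, took 4.78% (3.61 to 6.19). Skin had too few γ contigs, 4 WT and 48 KI cells, for this comparison.

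**Figure D1:**
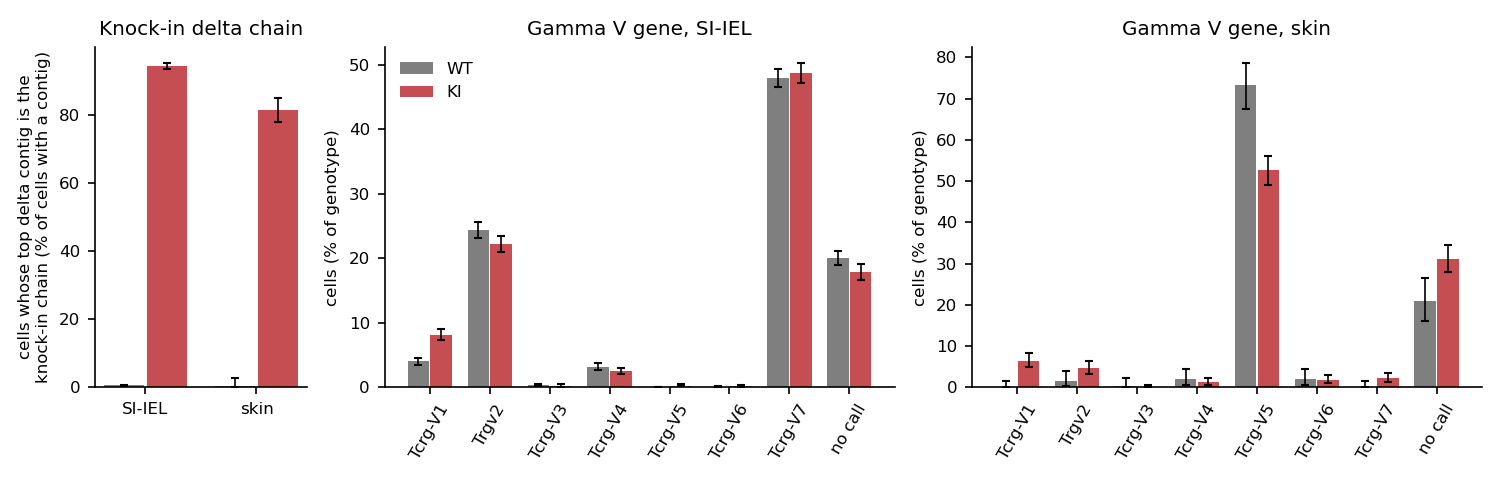
Left, share of cells whose top δ contig is the knock-in chain, in % of cells with a δ contig. Middle and right, share of cells with each γ V call in SI-IEL and skin, in % of the genotype. Bars are WT and KI cells of 1 pool each, lines are 95% Clopper-Pearson intervals. Tcrg-V7 was at 48.0% and 48.7% in SI-IEL, and Tcrg-V5 at 73.3% and 52.6% in skin.

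Cell states differed between genotypes in the intestine. SI-IEL cluster 2, led by Tgm2, Tcf7, Id3 and Xcl1, held 34.5% of KI cells (33.0 to 36.0) and 8.13% of WT cells (7.40 to 8.92). Tcf7 and Id3 encode transcription factors of naive and long-lived T cells. Cluster 0, led by Gzmk and Scin, held 37.7% of WT (36.4 to 39.1) and 14.2% of KI cells (13.1 to 15.3). Cluster 4, a stressed or activated cluster led by Hspb1, Atf3 and Pdcd1, held 1.76% of WT and 7.74% of KI cells. The naive cluster 9, with Ccr7, Lef1 and S1pr1 among its leading genes, was rare, with 14 WT (0.274%) and 36 KI cells (0.896%). Cluster 1, led by Tyrobp and Cd200r2, held 25.9% and 23.1%, stressed or activated cluster 3 19.1% and 12.7%, cycling cluster 6 1.69% and 1.05%, and interferon cluster 8 0.745% and 0.946%. Cluster 5, with a median of 913 UMIs, held 3.92% and 3.71%, and stressed or activated cluster 7, led by Ccl4 and Egr2, 0.784% and 0.921%. A B and plasma cell cluster, 10, had 2 WT and 12 KI cells, although the gate required CD3 and TCRδ. Clustered without the 200 most differing genes, cluster 2 held 7.78% and 34.0% and cluster 0 37.1% and 15.6%.

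KI-tagged skin cells held cell states that were rare or absent in WT skin. The type 1 cytotoxic cluster 4 was led by Ms4a4b and Ccl1, with the markers Tbx21, Ifng and Cxcr3. It had 47 KI cells (5.90%, 4.37 to 7.77) and 0 of 258 WT cells, which allows a share of up to 1.16%. Its name rests on type 1 markers. Of the 47 cells, 1 had Gzma, 1 Gzmb, 27 Gzmc and 5 Ccl1 UMIs. The NKT-like cluster 5, with Zbtb16, Icos and Slamf1, had 33 KI cells (4.15%, 2.87 to 5.77) and 1 WT cell. Zbtb16 encodes PLZF, a transcription factor of innate-like T cells. Of the KI cells with a δ contig, 35 of 37 in cluster 4 and 26 of 26 in cluster 5 carried the knock-in chain. Cluster 7, also type 1 cytotoxic by its markers and led by Gzma, Ccl5 and Cd8a, had 20 KI cells (2.51%) and 0 WT cells, and only 3 of its 16 cells with a δ contig carried the knock-in chain. The type 17 cluster 2, with Il17a, Il17f and Il23r, held 33 WT (12.8%, 8.97 to 17.5) and 49 KI cells (6.16%, 4.59 to 8.06). Clusters 0 and 1 held 54.3% and 23.3% of WT and 43.8% and 26.6% of KI cells. Myeloid cluster 3 held 14 WT (5.43%) and 60 KI cells (7.54%), cycling cluster 6 7 and 25 cells, and cluster 8, with keratinocyte genes such as Krt14, 3 and 1. In cluster 3, 33 of 74 cells had a δ contig, and 25 of the 26 such KI cells carried the knock-in chain. Its barcodes can therefore not all be read as myeloid cells that the CD3 and TCRδ gate would remove. Without the 200 most differing genes, 3 WT cells fell in cluster 4 and 2 in cluster 5.

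KI skin cells with Tcrg-V1 or Trgv2 were spread over the clusters. Of 51 Tcrg-V1 cells, 12 were in cluster 0, 6 in cluster 1, 13 in cluster 4 and 11 in cluster 5. Of 37 Trgv2 cells, 4 were in each of clusters 0, 1 and 4, 10 in cluster 5, 8 in cycling cluster 6 and 5 in cluster 7.

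**Figure D2:**
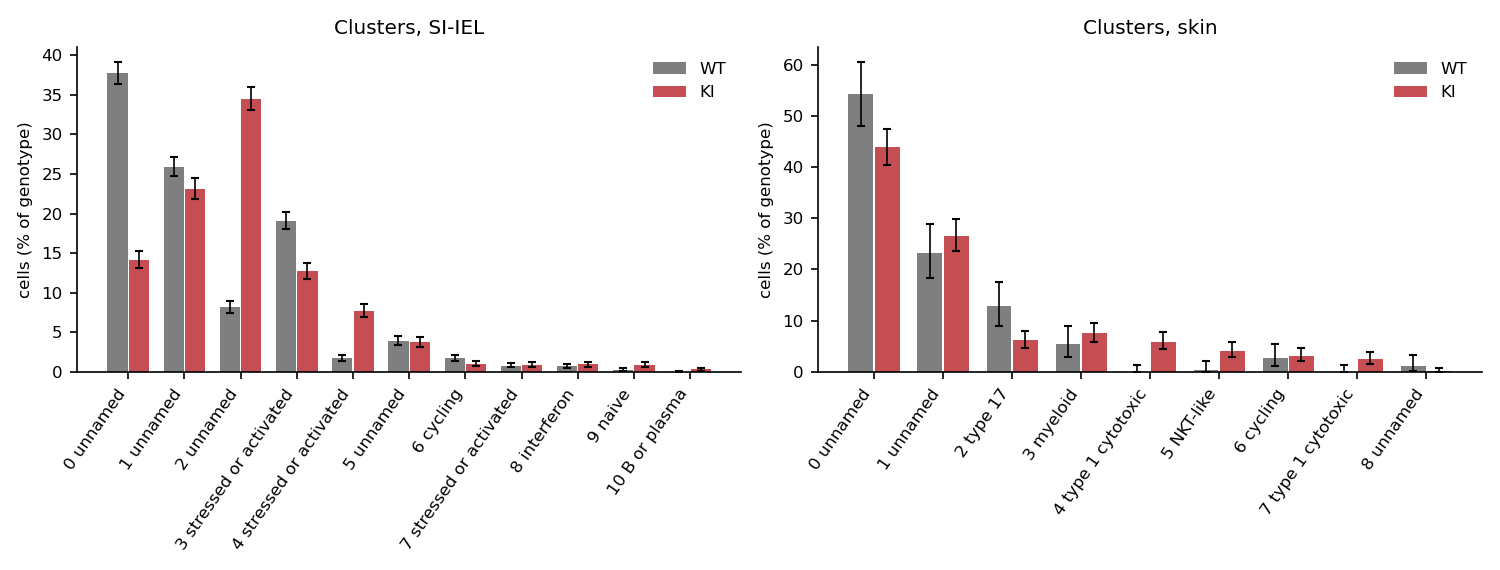
Share of WT and KI cells in each cluster, in % of the genotype, for SI-IEL and skin. Bars are 1 pool each and lines are 95% Clopper-Pearson intervals. SI-IEL cluster 2 held 8.13% of WT and 34.5% of KI cells, and skin clusters 4 and 5 held 0 and 1 WT cells.

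By gene, SI-IEL KI cells expressed more genes of naive and recirculating T cells and less of granules than WT cells. The naive and recirculating list had a median log2 ratio of 0.96 (counting interval 0.82 to 1.20), at percentile 100 of the random lists, with 9 of 10 measured members higher. Among them were the homing receptor Ccr7 (1.65) and the transcription factors Tcf7 (1.58) and Lef1 (1.14), with Igfbp4 highest (2.10) and Rflnb lowest (0.12). The cytotoxic granule list had a median of −0.36 (−0.44 to −0.33), at percentile 0, with 8 of 10 members lower. Granzymes Gzmk (−1.24), Gzma (−0.57) and Gzmb (−0.48) and the pore former Prf1 (−0.68) were lower, and Ctsw (0.12) was higher. Within clusters 0, 1, 2 and 3 the median of the granule list was 0.01, −0.03, −0.16 and 0.05, and that of the naive list within cluster 2 was 0.53. The Xist-positive WT cells without Y-linked UMIs gave 0.97 for the naive and −0.37 for the granule list. Lists of other cell types were higher in KI cells too, with αβ T cells at 0.36 (percentile 99.85), intestinal epithelium at 1.14 and B and plasma cells at 1.78. Without cluster 10 the B and plasma cell list was at −0.047.

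Of the 10 genes highest in SI-IEL KI cells, 9 were genes of antibody-producing cells. These were Igkv5-43, Ighv1-26, Igkv1-117, Ighv9-3, Iglv1, Ighv1-74, Igkv6-23 and Igkv6-13, each with at least 98.0% of its UMIs in 1 cell, and Jchain (2.47), with 33.5% in 1 cell. The other was Tgm2, a transglutaminase (ENSMUSG00000037820, mm10 chromosome 2, 158116402 to 158146436), at 2.45 (2.30 to 2.88). The lowest were Igkv8-30, Ighv5-9 and Igkv8-27 (−0.98), Klra5 (−1.73), Scin (−1.44, ENSMUSG00000002565, chromosome 12, 40059769 to 40134228), Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), Gm156 (−1.11), Zg16 (−1.08), Hip1 (−0.82) and the chemokine Ccl3 (−0.80). Zg16, in 13 KI and 15 WT cells, had 71.6% of its UMIs in 1 WT cell, on which its direction rests, and was at 6.21 in Tcrg-V7 cells, with 98.6% in 1 KI cell. Igkv8-27, with 53.3% of its UMIs in 1 cell, was at 0.018 with cells of at least 1000 genes and at 1.05 against Xist-positive WT cells. Igkv8-30 had 1 KI and 4173 WT UMIs (log2 interval −17.05 to −9.27), and Ighv5-9 had its 1717 UMIs in 1 WT cell. Without cluster 10, Igkv5-43 was at −0.13, Iglv1 at −0.34, Igkv1-117 at −0.05 and Igkv6-13 at −0.10. The highest ratios were then Tgm2 (2.46), Id3 (1.72, 1.59 to 1.91), Fcgbp (1.71, 6 KI and 5 WT cells), Tcf7 (1.59), Xist (1.25), Xcl1 (1.16, ENSMUSG00000026573, chromosome 1, 164931644 to 164935527), Ms4a4b (1.06), Ltb (1.03), Rgs10 (1.00) and Cd160 (0.92). The lowest then also included Ccl4 (−0.78), Klre1 (−0.77) and Emp3 (−0.71).

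Genes of proliferation were lower and genes of stress higher in SI-IEL KI cells. The cell cycle list was at −0.47 (−0.56 to −0.36), percentile 0, with 14 of 16 members lower, from Mki67 (−0.83) to Pcna (−0.23), and Tubb5 higher (0.23). The stress and AP-1 list was at 0.32 (0.28 to 0.35), percentile 100, with 14 of 16 higher, led by Atf3 (0.99) and Fos (0.61). The RNA quality list, of transcripts such as mitochondrial genes and Malat1, was at 0.15 (percentile 95.7), with 6 of 9 members higher and 2 lower. The median of 13 mitochondrial genes was at 0.25. Higher values of these genes do not stand for better RNA quality. The type 1 effector list was at −0.18 (−0.30 to −0.14), percentile 0.01. Its members split, with Klrc1 (−0.69) and Ccl5 (−0.67) lower and the chemokine Xcl1 (1.16) higher. The type 17 list was at 1.36 (1.02 to 1.59), percentile 99.99, on 6 members, of which Tmem176a (1.63) had 45 KI and 8 WT UMIs. The type 17 transcription factor Maf was at 1.42, and Rora at −0.18. The type 17 median was 0.24 without a filter on UMIs, 0.62 with a pseudocount of 5 and 0.75 with equal weight per cell. The NKT-like list was at 0.35, percentile 99.84, with Zbtb16 (2.41) and Klrb1c (1.54) highest. Inhibitory receptors were at −0.22, percentile 0.08, with 6 of 9 lower, such as Havcr2 (−1.75) and Klrg1 (−1.05), and Pdcd1, which encodes PD-1, higher (2.24). Their median was −0.10 with at least 200 UMIs, and that of the granule list −0.24 without a filter. Medians of the residency list (−0.04, percentile 0.75), early T cell receptor response (0.05, 68.1), MHC class I (−0.08, 0.70) and type I interferon response (0.07, 81.2) were near 0.

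The highest skin ratios included genes of cytotoxic and type 1 lymphocytes, although the medians of both lists were near 0. Gzma had 2523 KI and 0 WT UMIs (at least 261-fold higher) and the chemokine Ccl5 3005 and 0 (at least 311-fold). Cluster 7 held 99.8% of these Gzma and 85.7% of these Ccl5 UMIs, and as its cells mostly lacked the knock-in chain, these UMIs cannot be read as expression of KI cells. Outside it, 257 Ccl5 UMIs lay in cluster 4 and 157 in cluster 3. KI cells with Tcrg-V5, none of them in cluster 7, had 380 in 15 cells against 0 in WT cells (at least 54.1-fold). Of these 380 UMIs, 38.2% were in 1 cell. Clusters 0 and 1 held 234 and 137 of the 419 KI Tcrg-V5 cells but only 2 Ccl5 UMIs each. The fold thus rests on few cells of other clusters and does not describe most Tcrg-V5 cells. Ifng, the type 1 cytokine, had 60 KI and 0 WT UMIs (at least 6.20-fold; ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), with 60% from cluster 4. Its regulator Tbx21 was at 2.55, with 110 KI and 5 WT UMIs (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331). Ccr8, a skin-homing chemokine receptor, was at 2.86 (2.25 to 3.70; ENSMUSG00000042262, chromosome 9, 120092114 to 120094906), with 40.2% of its KI UMIs from cluster 5 and 33.0% from cluster 4. Icos was at 1.64 and Gata3, a type 2 transcription factor, at 1.12.

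The other genes with the highest skin ratios were Mucl1, Ccl1, Ccl8, AW112010, Ms4a4b, Ccl4 (3.10) and C1qb (2.21). Ccl1 had 293 KI and 0 WT UMIs (at least 30.3-fold), 53.9% of them in cluster 4. They lay in few cells, with 158 in 5 cells of cluster 4, 86 in 1 cell of cluster 3 and 44 in 1 cell of cluster 6. AW112010 (118-fold, log2 interval 4.40 to 12.20) drew 70.7% of its KI UMIs from cluster 7, Ms4a4b (50.5-fold, 3.16 to 10.97) 61.3% from cluster 4 and C1qb 99.6% from myeloid cluster 3. Of the Ccl4 UMIs, 53.7% of those of KI cells and all 10 of WT cells lay in cluster 3, and 40.3% of those of KI cells in cluster 7. Mucl1 was in 3 and Ccl8 in 8 KI cells. The lowest were Mgp (1 WT cell), Dcn (−5.61), the Y-linked Ddx3y (−4.95), Plet1 (−4.40), Krt14 (−4.16), Plin2 (−3.74), Sparc (−3.38), Mt2 (−3.14), Aqp3 (−3.09) and Fxyd3 (−2.87). Krt14, Dcn and Fxyd3 were each in 4 WT cells, Plet1 in 5, Mt2 in 7, Plin2 in 17, Sparc in 21 and Aqp3 in 23. Krt14, Plet1 and Sparc had 50.8%, 50.7% and 57.9% of their UMIs in 1 cell. The keratinocyte list was at −1.53, percentile 0, and the myeloid list at 0.91, percentile 100. Without clusters 3 and 8, Tyrobp (23.9-fold on 2 WT UMIs, log2 interval 2.70 to 7.64), Cd27 (2.91) and Gzmb (2.23) entered the highest ratios. Cluster 7, which was kept, held 68.1% of the Gzmb UMIs of KI-tagged cells, which cannot be read as expression of KI cells. Il22 (−2.50, 4 KI and 6 WT cells), Cxcl2 (−2.47), Abi3bp (−2.26), Sidt1 (−1.66), Klf9 (−1.36) and Timp1 (−1.34) entered the lowest ratios.

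Among the skin lists, the type 17 list was at −0.23 (−0.45 to −0.06), percentile 0.68, with 6 of 15 members lower and 0 higher. Lower were the cytokines Il22 (−2.49) and Il17a (−0.95), the receptor Il23r (−1.37) and the kinase Blk (−1.46), and Maf was at 0.19. Within type 17 cluster 2 its median was −0.10. Over all cells it was −0.044 with at least 200 UMIs, −0.56 with equal weight per cell and −0.48 with the same γ V shares. Among Xist-positive WT cells without Y-linked UMIs, Il22 was at 0.61 in place of −2.49. MHC class I was at 0.37 (0.25 to 0.64), percentile 99.98, with 6 of 10 higher, such as Psmb9 (1.12), H2-Q7 (0.87) and B2m (0.58). The type I interferon list was at 0.87 (0.39 to 1.21), percentile 100, with 5 of 7 higher, led by Ifi27l2a (1.64), and Irf7 at −0.35. The cell cycle list was at 0.36, percentile 99.94, led by Pclaf (1.76) and Mki67 (1.66). Its median was 0.017 against Xist-positive WT cells, 0.19 with equal weight per cell and 0.83 without the 20 most frequent of the 28 WT δ clones. Leaving out these 20 removes most WT cells with a δ contig, so such values do not single out frequent clones. The early T cell receptor response was at −0.31, percentile 0.06, with 5 of 10 lower and Myc lowest (−1.24, or 0.29 without clusters 3 and 8). Inhibitory receptors were at −0.41, percentile 0.21, with 4 of 6 lower, and at 0.14 without a filter on UMIs, 0.30 without those clones and −0.17 against Xist-positive WT cells. Medians of the type 1 (0.07, 69.3), NKT-like (0.12, 87.7), naive (0.21, 92.7), cytotoxic granule (0.04, 68.9), residency (0.01, 29.4) and stress lists (−0.05, 13.9) were near 0. Without those clones, type 1 was at 0.56, naive 0.73, granule 0.48 and stress 0.10, and the granule median was 0.28 without a filter on UMIs and 0.22 with the same γ V shares.

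**Figure D3:**
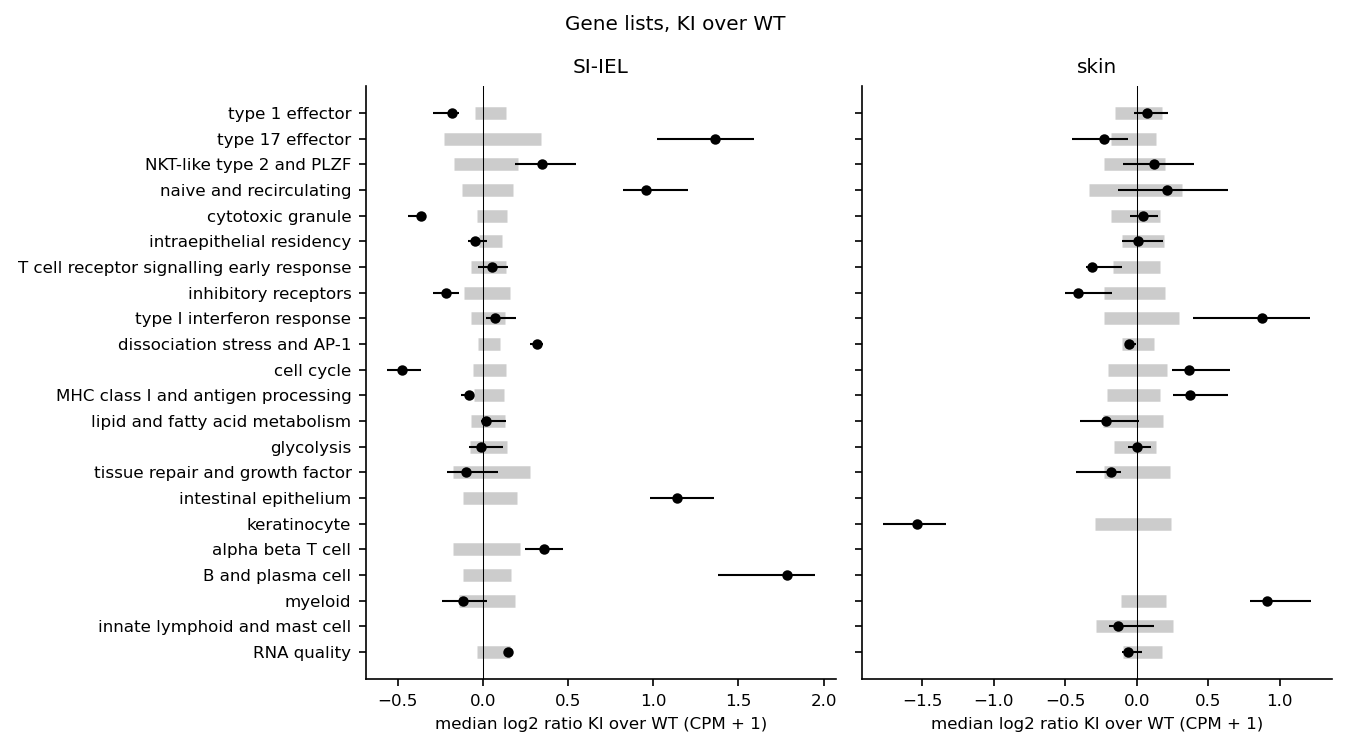
Median log2 ratio KI over WT of each gene list in SI-IEL and skin. Points are medians with counting intervals, grey bars the central 95% of 10000 random lists of the same size and expression. In SI-IEL the naive and recirculating list was at 0.96 and the cytotoxic granule list at −0.36.

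Within γ V genes, the SI-IEL difference in granule genes was smaller in Tcrg-V7 than in Tcrg-V1, Trgv2 and Tcrg-V4 cells. The naive list was at 1.33 in Tcrg-V1, 1.43 in Trgv2 and 0.44 in Tcrg-V7 cells, and the granule list at −1.35, −0.68 and −0.09, with −0.68 in Tcrg-V4 cells, where the naive list had 2 measured members. The WT groups differed in clonality, as 1 δ CDR3 held 33.5% of Tcrg-V1, 19.4% of Trgv2 and 3.87% of Tcrg-V7 cells with a δ contig. Tcf7 was higher in all 4, at 1.68 (Tcrg-V1), 1.78 (Trgv2), 1.52 (Tcrg-V4) and 1.35 (Tcrg-V7), and Id3 at 1.97, 2.19, 1.77 and 1.33. Xcl1 was at 2.09, 1.87, 1.67 and 0.44. Gzmk was at −4.71, −2.03, −2.52 and −0.58, Gzma at −2.69, −1.24, −0.91 and −0.17, and Gzmb at −2.43, −1.37, −0.45 and 0.03. Cluster 2 held 70.9% of KI and 16.1% of WT Tcrg-V1 cells, 51.7% and 9.42% of Trgv2 cells and 20.8% and 7.48% of Tcrg-V7 cells. In Tcrg-V1 cells Zbtb16 had 50 KI and 0 WT UMIs (at least 8.95-fold higher; ENSMUSG00000066687, chromosome 9, 48654297 to 48836222). These 7 genes were chosen for this comparison after their values in all cells were seen, and the differences between V genes were not tested.

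Tcrg-V1 and Tcrg-V7 cells also differed within a genotype. In KI cells, Tcrg-V1 over Tcrg-V7 gave 1.43 for the naive, −0.90 for the granule, −1.32 for the inhibitory receptor and 0.62 for the NKT-like list. The genes Zbtb16 (3.74), Slamf6 (3.14), Tgm2 (2.87), Lef1 (2.86) and Ms4a4b (2.68) were highest, and Gzmk (−3.83) was among the lowest. In WT cells the naive list was at 0.71 and the granule list at −0.11, with Ms4a4b (1.87), Thy1 (1.69) and Rgs10 (1.57) among the highest and Spp1 (−3.03) and Klrb1a (−2.39) among the lowest genes. The WT cell cycle list was at −2.16, or −1.21 with its 3 members at 0 UMIs set at their bound. In skin Tcrg-V5 cells, KI over WT gave −0.00 for the granule list, −0.91 for Xcl1, 1.25 for Gzmb and −0.24 for Tcf7.

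**Figure D4:**
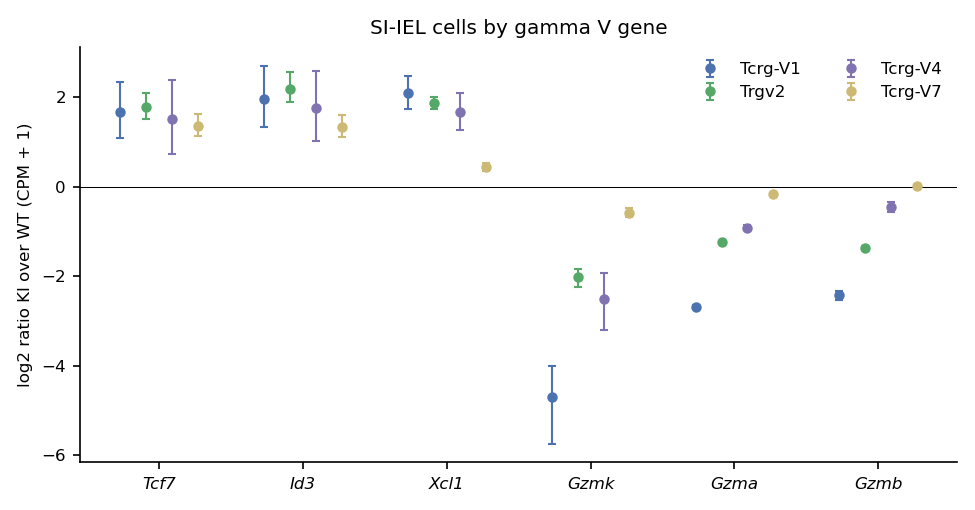
Log2 ratio KI over WT of Tcf7, Id3, Xcl1, Gzmk, Gzma and Gzmb in SI-IEL cells by γ V gene, with counting intervals. Gzmk ran from −4.71 in Tcrg-V1 to −0.58 in Tcrg-V7 cells.

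The tissues were compared within each genotype. Areg, a growth factor of tissue repair, was at 11.08 in WT and 10.88 in KI cells (skin over SI-IEL), and Mest at 10.23 and 9.64. S100a4 (at least 7986-fold in WT, 9.25 in KI), Lmna (WT, 3 SI-IEL UMIs, log2 interval 10.75 to 14.58), Ramp3 (9.71, WT), Fermt2 (at least 3180-fold, KI) and Ctla2a (9.03, KI) were also higher in skin. Ccl5, Gzma, Cd8a and Gimap4 had 0 UMIs in WT skin and were at least 13801-, 13055-, 515- and 301-fold lower than in SI-IEL. AW112010 was also lower, with 1 UMI in WT skin and 52559 in SI-IEL (log2 interval −17.13 to −9.34). In KI cells the lowest were genes of antibody-producing cells, Iglv1, Igkv5-43, Igkv1-117, Ighv1-26 and Jchain. The type 17 list was at 6.19 in WT (9 of 9 higher in skin; 6.39 with 2 members at their bound) and 4.40 in KI cells (13 of 13), and the repair list at 1.87 and 1.80. The residency list was at −1.996 and −1.74, MHC class I at −2.15 and −1.75, and type I interferon at −3.05 (−2.77 at the bound) and −2.53. The NKT-like list was at 3.47 and 2.70 and the early T cell receptor response at 2.18 and 1.53. Lists of other cell types and of stress differed too. Myeloid was at 5.69 and 5.47 (5.62 at the bound), keratinocyte 5.09 and 3.61, innate lymphoid and mast cell 2.27 and 2.20, and stress 1.45 and 1.20. Lower in skin were intestinal epithelium, at −2.79 and −3.305 (−1.35 and −3.24 at the bound), B and plasma cells, at −5.09 and −3.41 (−4.76 and −3.36), and αβ T cells (−0.90, KI). The naive list was at 0.46 in WT (9 members) and −0.99 in KI cells (11), and type 1 at −1.15 (12) and 0.28 (14). The medians of the genotypes thus rest on different members, and the KI-tagged skin cells include cluster 7. The median gene was at −0.60 and −0.58 (−0.37 and −0.21 with TMM), and tissue and library cannot be separated here. After thinning cells to 1000 UMIs the WT naive list was at −0.013.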

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

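Of the tests in this part, the one on Y-linked UMIs was set before its result was seen, and those on shared barcodes and on the knock-in chain in cluster 7 were chosen after the result was seen. For 10 genes of the fixed lists or named genes, the KI over WT log2 ratio had opposite signs in skin and SI-IEL, and the difference between tissues was not tested. The chemokine genes Ccl3 and Ccl4 were at 2.64 and 3.10 in skin, on 4 and 10 WT UMIs, and at −0.80 and −0.79 in SI-IEL. Of the skin Ccl4 UMIs, 161 of 300 in KI-tagged and 10 of 10 in WT cells lay in myeloid cluster 3. The chemokine Ccl5, the granzyme Gzma and the integrin Itgax had 0 UMIs in WT skin and were at least 311-, 261- and 5.79-fold higher in KI-tagged skin cells. Their values with the pseudocount, 9.88, 9.63 and 4.21, are no measured ratios. In SI-IEL they were at −0.67, −0.57 and −0.69. The proliferation gene Mki67 was at 1.66 in skin and −0.83 in SI-IEL. Among inhibitory receptors, Havcr2 was at 0.85 in skin and −1.75 in SI-IEL, and Pdcd1 at −0.53 and 2.24. Without the 20 most frequent WT δ clones, skin Pdcd1 was at 0.19. WT skin had only 28 δ clones in 197 cells with a contig, so this leaves out most of these cells. It cannot tell whether the sign of Pdcd1 depends on frequent clones. The chemokine Xcl1 was at −0.84 and 1.16, and the interleukin 2 receptor Il2ra at −0.76 and 0.59.

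The Gzma and Ccl5 UMIs of KI skin came mainly from the 20 cells of cluster 7, which expressed genes of intestinal γδ T cells such as Ccr9, Cd8a and Itga1. Barcodes shared with the SI-IEL library as the main source are excluded, since 10% of these cells (2 of 20, 1.23 to 31.7) had such a barcode. Cells of the KI mice as the main source are excluded too. Only 18.75% of the top δ contigs (3 of 16, 4.05 to 45.6) carried the knock-in chain, against 83.7% (395 of 472) in the other KI-tagged skin cells. The values were consistent with WT SI-IEL cells that carried the KI tag. Y-linked UMIs were found in 30% of the cells (6 of 20, 11.9 to 54.3), in 0% of the other KI-tagged skin cells and in 25.1% of WT SI-IEL cells. Of 13 cells with another δ CDR3, 12 had a CDR3 that was also found in SI-IEL WT cells and 4 one found in SI-IEL KI cells, against 6 and 0 of 77 among the other KI-tagged skin cells. How such cells would have come into the skin library remained open.

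In receptor loci used in no comparison, TRB, IGH, IGK and IGL, contigs were present, 12480 in SI-IEL and 1513 in skin. Of these, 2 were productive, both of IGH in SI-IEL. No control samples were available for these loci.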

How the results depend on the processing

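The alternatives chosen after the data were seen were those on the 200 genes, clusters of other cell types, skin cluster 7, sex, γ V shares for the lists and frequent WT δ clones. The 12 alternative values for cell numbers and 8 for diversity were within 1.5 times the value given, but not always within its counting interval. Without the cell filter, SI-IEL held 5289 WT and 4161 KI cells, and with clones by nucleotide sequence KI SI-IEL had 540 γ clones in place of 425. All 40 values for γ V shares stayed within their counting interval. The same held for 10 of 16 values for the knock-in chain, 228 of 264 for cluster shares, 1258 of 1547 for genes, 476 of 570 for gene lists, and 33 of 40 and 37 of 88 for genes and lists by tissue. Of the remaining values, 22 gene, 7 list and 1 tissue list value reversed and the others moved. A main cluster that no alternative cluster matched gave no value, so resolution 0.3 gave 30 cluster shares and seed 1 gave 40. Alternative clusters were matched to the main cluster with which they shared most cells, which favours agreement. Values of SI-IEL without Scrublet doublets could not move, since Scrublet marked 0 barcodes there, and show nothing on stability. Alternatives for the γ contig filter, cells with exactly 1 γ contig and the source of the V call gave no value, because the contigs name TRGV2 alone. In skin, cell number limits what can be seen, as 0 of 258 WT cells allows a share of up to 1.16% (3 cells). Where no construction is named, the cause was not tested.

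With any δ contig counted, the knock-in chain was in 1.11% of WT and 98.1% of KI SI-IEL cells and 89.96% of KI skin cells. With at least 3 UMIs per contig, it was in 0% of WT and 76.0% of KI skin cells, and with the 80% tag ratio rule in 0% of WT skin cells.

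Cluster shares are given as WT and KI. At resolution 0.3, where clusters merge, SI-IEL cluster 0 held 65.0% and 38.6%, cluster 2 9.94% and 42.6%, cluster 5 2.59% and 2.49%, cluster 8 0.498% of KI cells, and skin cluster 0 77.9% and 70.6%. At resolution 1.0, SI-IEL cluster 0 held 34.3% and 13.1%, and clusters 1 and 7 held 28.5% and 1.12% of WT cells. With T cell receptor genes kept, SI-IEL cluster 0 held 33.0% and 10.3%, cluster 1 30.4% and 27.1%, cluster 8 0.572% of KI cells, skin cluster 5 0% of WT cells, and skin clusters 0 and 1 47.6% and 22.7% of KI cells. With the 80% tag ratio rule, SI-IEL cluster 0 held 33.6% and 12.0%, cluster 1 29.8% and 25.1%, skin cluster 0 63.0% and 56.9%, skin cluster 1 16.7% and 13.7%, and skin cluster 5 0% of WT cells. Without the 200 genes, SI-IEL cluster 5 held 2.61% and 2.51%, cluster 8 1.16% of WT cells, cluster 0 15.6% of KI cells, and skin clusters 0 and 1 50.3% and 21.2% of KI cells.

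Log2 ratios KI over WT follow. In SI-IEL, the stress list was at 0.27 and MHC class I at −0.13 with DESeq2 as well as with TMM factors, and Psmb8 at −4.722e-04 with TMM. MHC class I was at −0.053 with the total without T cell receptor, mitochondrial and ribosomal protein genes. With at least 200 UMIs, the SI-IEL naive list was at 0.73, inhibitory receptors at −0.10, skin type 1 at −0.066 and skin type 17 at −0.044. Without a filter, SI-IEL type 17 was at 0.24, naive 0.75 and cytotoxic −0.24, skin cytotoxic 0.28 and skin inhibitory receptors 0.14. SI-IEL type 17 was at 1.82 with a pseudocount of 0.1 and 0.62 with 5, where naive was at 0.76. With cells of at least 1000 genes, Igkv8-27 was at 0.018. With equal weight per cell, SI-IEL type 17 was at 0.75, cell cycle −0.64, skin type 17 −0.56, stress 0.00839 and cell cycle 0.19. The 80% tag ratio rule gave −0.089 for skin stress. With the same γ V shares, skin type 17 was at −0.48, cytotoxic 0.22 and stress −0.00500.

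Against WT cells with Xist and without Y-linked UMIs, SI-IEL Igkv8-27 was at 1.05, Epcam 0.077, and by construction Xist −0.21, Ddx3y 0.33 and the sex-linked list 0.23. SI-IEL type 1 was at −0.12, type 17 1.59, stress 0.37 and cell cycle −0.66. In skin, Ddx3y was at 1.17, Xist −0.42, Il22 0.61, inhibitory receptors −0.17, stress 0.066 and cell cycle 0.017. Without clusters of other cell types, SI-IEL Igkv5-43 was at −0.13, Igkv1-117 −0.047, Iglv1 −0.34, Igkv6-13 −0.10, Cd79a −0.047, Cd74 −0.24, the B and plasma cell list −0.047 and type 17 1.00, and skin Ccr7 −0.16, Myc 0.29, Gm42418 −0.013 and stress −0.081. Without the 20 most frequent WT δ clones, SI-IEL type 1 was at −0.14, naive 0.82, cytotoxic −0.28 and MHC class I −0.051. WT skin had only 28 δ clones, and 1 of these 20 alone held 142 of the 197 WT cells with a contig. The skin values thus leave out most of these cells and do not single out frequent clones. There Il22 was at 0.19, Pdcd1 0.19, Cd74 −0.88, Gm42418 −0.050, type 1 0.56, naive 0.73, cytotoxic 0.48, inhibitory receptors 0.30, stress 0.10 and cell cycle 0.83.

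By tissue, skin over SI-IEL, TMM factors gave the residency list at −1.75 in WT and −1.35 in KI cells, and type 17 4.75 and MHC class I −1.35 in KI cells. Thinned to 1000 UMIs, WT type 17 was at 6.4998, residency −1.44 and naive −0.013.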

Other observations

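Of the tests in this part, those on sex and on frequent WT clones were set before their results were seen, and those on γ V composition and on Trdv4 were chosen after the result was seen. In KI skin, 10 of 15 cells with Tcrg-V6, a γ V gene of interleukin 17 producers, were in type 17 cluster 2. Skin cluster 1 was led by genes that included the type 2 cytokine Il13. Among metabolic lists in SI-IEL, lipid metabolism was at 0.02 (percentile 42.1), with the fatty acid binding protein Fabp2 at 1.41 and Sqle at −0.13, and glycolysis at −0.01 (18.8), with Pgam1 at 0.29 and Slc2a3 at −0.31. In skin, lipid metabolism was at −0.22 (3.90), with Fabp5 at 1.11 and Plin2 at −3.74, and glycolysis at 0.0049 (61.1). The tissue repair list was at −0.10 (8.29) in SI-IEL, with Csf2 at 1.19 and Hbegf at −0.39, and at −0.18 (5.90) in skin.

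Lists of other cell types and of RNA quality were also measured. In SI-IEL, the epithelial gene Reg3b was at 2.57 with 68.5% of its UMIs in 1 cell. Of the αβ T cell genes, Cd40lg was at 2.44 and Trac at −0.48. The myeloid list was at −0.12 (percentile 4.24). Sex-linked genes were at −3.95 (0). In skin, innate lymphoid and mast cells were at −0.13 (16.2) and RNA quality at −0.06 (6.97). The median ribosomal protein gene was at 0.12 in SI-IEL and 0.13 in skin.

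The naive list lay above the granule list by 1.32 (1.20 to 1.58) in SI-IEL KI over WT cells. The sex of the mice as a source of 50% or more of this lay outside the counting interval, but is not excluded. WT cells with Xist over WT cells with Y-linked UMIs gave 0.49 (0.14 to 0.64), just under the bound of 0.66, so a smaller part may stem from sex. These 2 groups of cells come from different mice, and the interval leaves out differences between mice, so this test does not exclude a larger part. With only the Xist-positive WT cells without Y-linked UMIs as reference, KI cells kept both list medians within their counting intervals. These were 0.82 to 1.20 for the naive and −0.44 to −0.33 for the granule list. For these 2 lists this argues against sex as a source of 50% or more, apart from differences between mice. With equal γ V shares the difference was 1.24 (1.14 to 1.49). Without 1332 of 5102 WT cells, those of the most frequent WT clones, it was 1.102 (0.97 to 1.32). Within these pools this argues against called γ V composition and the clones left out as sources of 50% or more. It does not exclude them, as these intervals too leave out differences between mice. No γ V call was made in 20.01% of WT and 17.9% of KI cells. A further 678 WT cells had no δ contig and could not be assigned to a clone. An effect of the δ chain, or of other differences between these pools of mice, stays open and was not tested.

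Trdv4 UMIs were found in KI-tagged skin cells although the knock-in chain uses another V gene. Free RNA as the main source is excluded, since it would give all clusters a like share. At 1000 UMIs per cell, Trdv4 was found in 26.4% of cluster 0 cells (91 of 345, 21.8 to 31.4), in 0 of 33 cluster 5 cells (0 to 10.6) and in 10% of myeloid cluster 3 cells (6 of 60, 3.76 to 20.5). Clusters 4 and 6 lay at 8.51% and 16% (4.54 to 36.1), so free RNA stays open for a part. Wrongly tagged WT cells as the main source are excluded, since 78.4% (58 of 74, 67.3 to 87.1) of the cells with at least 5 Trdv4 UMIs and a δ contig carried the knock-in chain. A retained endogenous rearrangement may explain them and stays open. Of the knock-in cells with at least 5 Trdv4 UMIs, 65.5% (38 of 58, 51.9 to 77.5) also had a TRDV4 contig, but contigs and UMIs come from the same cDNA, so this does not decide.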
